A study of Gallus gallus with 2 samples.

How the data were processed

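Gene expression was measured in cells of the chicken neural tube on an Affymetrix chicken array, with biotin as the label. Per the labels' protocols, embryos were electroporated at Hamburger-Hamilton stage (HH) 9 with plasmids that carry GFP, the neural tube was dissociated at HH11, and GFP-positive cells were sorted before total RNA was extracted. The labels also state an incubation of 2 days, which does not obviously go together with harvest at HH11, so the stage of the cells is not certain. Both statements are given here as the labels give them. Labelled RNA was made with a 3' IVT Express kit from 100 ng of total RNA, per the labels' protocols. The control group is 1 sample that received the empty plasmid, and the knockdown group is 1 sample that received plasmids for short hairpin RNAs against Sox4 and Sox11. How many embryos were pooled in a sample is not given in the sources used here.

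The deposited values are linear signal intensities of probe sets, made with MAS5 5.0 per the submitters' processing notes. The mean after removal of the highest and the lowest 2% of probe sets was 1000.3 on the control array and 1000.3 on the knockdown array, so the deposited intensities had been scaled to an equal trimmed mean. No detection calls were used. The values were taken as deposited, and log2 was taken once.

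The array holds 38535 probe sets, of which 37693 are chicken probe sets by their names, 96 are array controls, 57 are for reporter sequences and 689 are for viral sequences. Gene symbols came from the platform annotation and were updated through Entrez gene numbers with a RefSeq gene table of the assembly GRCg7b, from which no coordinates were used. Of the chicken probe sets, 27166 had 1 symbol, 177 had several and 10350 had none; the last 2 kinds were left out of gene counts. The 13008 genes were each represented by the probe set with the highest mean log2 signal over both arrays. A gene was called measured when this mean was at or above the median over chicken probe sets, which corresponds to a signal of 118, and 9303 genes passed. Background was the 95th percentile of 687 viral probe sets without a chicken gene, at a signal of 63.6 on the control array and 65.8 on the knockdown array. Where a gene lay at or below background on 1 array, its fold was computed against that background and is given as a lower bound.

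With 1 sample per group there is no replicate spread, no test was made and no p-value is given. Genes were counted by size, at least 2-fold higher or lower, and the count is a description of these 2 arrays. Yardsticks were the log2 ratios of control transcripts, and the spread of log2 ratio between different probe sets of a gene, computed in 10 equal groups of mean signal over 3853 genes with several measured probe sets. For a gene list, the median log2 ratio of the measured members was set against the medians of 10000 random lists of the same size, matched on mean signal in 20 equal groups. Its percentile among them describes these 2 arrays and is no p-value. Intervals of a median are 95% bootstrap intervals over genes, with 10000 draws, and cover the spread between genes only.

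The count rule was tested on simulated data for the knockdown against control comparison, with 9303 genes and the probe set spread as noise. Genes past 2-fold in the right direction were 10% of those simulated with a 1.5-fold difference, 46% at 2-fold, 98% at 3-fold and 100% at 4-fold. Of 9055 simulated unchanged genes, 192 (2.12%) passed 2-fold. Of 40 simulated unchanged lists, 2 lay outside the central 95% of random lists. These lists were drawn at random from genes with independent noise. They check the computation and say nothing about lists whose genes move together.

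The samples' groups, the tests' design, 29 gene lists and the rule for named genes were fixed before the data were examined. The rule names the targets; the 12 highest and 12 lowest measured genes without locus or open reading frame names; the 5 highest and 5 lowest in the brightest 10% of all genes; in each list up to 4 measured members with the largest size of log2 ratio; and fixed examples (TUBB3, MAP2, ELAVL4, STMN2, NEFM, DCX, NEUROG2, NEUROD4, DLL1, SOX2, PAX6, HES5, TEAD2, PROX1, GAPDH). It gave 141 genes, of which those most useful to a comparison are given. SOX12 and TEAD2 were not matched to a probe set by symbol and were not analysed here. List members were matched by symbol and, failing that, through unambiguous synonyms of the RefSeq table, which in a few cases lead to a related gene (ALAS2 to ALAS1, KRT19 to KRT24). Another 2 lists, of contractile muscle genes and of muscle and heart regulators, were written after the values had been seen; they are described in the closing section, and the contractile list also enters a count without marker genes in the results.

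Alternatives were median centring, equal trimmed means, quantile normalization, loess centring with a span of 0.3, a constant of 34.1 added to both signals, a floor at background, other filters on low signal, other rules for the probe set, and thresholds of 1.5-fold and 3-fold. The mean over the measured probe sets of a gene, counts without the marker and contractile genes, and the Sox list without SOX4 and SOX11 were added after seeing the data. List medians under the alternatives were set against 2000 random lists each. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.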

Results

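Expression was compared between GFP-sorted neural tube cells of chicken embryos that received an empty GFP plasmid (1 control array) and cells that received plasmids for short hairpin RNAs against Sox4 and Sox11 (1 knockdown array). By the series' title, the comparison looks for genes regulated by SoxC factors, the transcription factor group of Sox4, Sox11 and Sox12, during neurogenesis in the spinal cord. The median signal of chicken probe sets was 113 on the control array and 134 on the knockdown array, and 62.5% and 65.5% of chicken probe sets lay above background. Log2 signals correlated between the arrays with r = 0.971 across measured chicken probe sets, which are not independent replicates. There were no replicates, so no difference below was tested, "higher" and "lower" describe these 2 arrays, and the number of arrays limits the precision of every value.

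Both targeted genes had lower signal on the knockdown array. SOX4 had a signal of 6604 in the control and 3157 in the knockdown (log2 ratio -1.06, 2.09-fold lower), and SOX11 had 4552 and 2790 (log2 ratio -0.71, 1.63-fold lower). Neuronal genes were lower with them, among them ISL1, ELAVL4 and NEFM, while the neural progenitor list as a whole was not. Of 48 pan-neuronal genes, 42 were below 0, with a median log2 ratio of -0.60. The lower signals of SOX4 and SOX11 therefore do not by themselves show that the hairpins acted. Markers of blood and surface ectoderm were higher on the knockdown array. Medians of endothelium and of notochord and endoderm were above 0 under every setting run but above the central 95% of random lists under some only, and ACTC1, cardiac alpha-actin, had the highest log2 ratio of all measured genes. SOX4 and SOX11 each have another probe set that lay below background on both arrays (4.8 and 43 for SOX4, 4.4 and 27.9 for SOX11), which gives no fold.

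Genes of the pan-neuronal list were lower on the knockdown array, with 24 of 48 measured members at least 1.5-fold lower, 5 at least 2-fold lower and 1 at least 2-fold higher. Their median log2 ratio was -0.60 (95% bootstrap interval -0.74 to -0.43), below all 10000 matched random lists, whose central 95% ran from -0.11 to 0.10. ELAVL4, a neuronal RNA-binding protein, had signals of 20538 and 10781 (log2 ratio -0.93), and both of its measured probe sets were lower. NEFM, the medium neurofilament, had a log2 ratio of -0.78, the neuronal tubulin TUBB3 -0.97, the microtubule regulators STMN2 and DCX -0.74 and -0.75, and MAP2 -0.58. The transcription factors EBF1 and EBF3 had log2 ratios of -1.45 and -1.20, and the RNA-binding protein gene ELAVL2 -1.25. NRCAM, a neuronal adhesion molecule, went the other way, with 256 in the control and 625 in the knockdown (log2 ratio 1.29).

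The list of genes linked to SoxC factors in earlier work shares 8 members with the pan-neuronal list. Of its 12 measured members, 9 were at least 1.5-fold lower, 2 at least 2-fold lower and 0 at least 1.5-fold higher, with a median log2 ratio of -0.78 (-0.95 to -0.66), below all 10000 random lists. The 2 were ISL1, a motor and sensory neuron factor (4160 and 1562, log2 ratio -1.41), and PROX1, expressed in neurons that begin to differentiate (2922 and 1336, log2 ratio -1.13). Of 21 measured transcription factors and markers of spinal neuron subtypes, 4 were at least 2-fold lower and 0 higher (median log2 ratio -0.45, -0.85 to -0.13, below all random lists). That median was -0.13 with the mean of all probe sets (percentile 0.5) and -0.70 with quantile normalization. The 4 were ISL1, VSX1 (log2 ratio -1.39), the inhibitory transporter gene SLC32A1 (-1.17) and the interneuron factor PAX2 (-1.08). Proneural and Notch pathway genes had a median log2 ratio of -0.41 (-0.59 to -0.24) over 21 measured members, below all random lists, but -0.060 with the mean of all probe sets, inside their central 95% (percentile 4.25). Of these genes, 8 were at least 1.5-fold lower, among them NEUROG1 (-1.17), NHLH1 (-0.98), NEUROG2 (-0.91) and the Notch ligand gene DLL1 (-0.73). NEUROD4 lay below background on both arrays.

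These neuronal differences stood beside a difference between the arrays in labelled RNA. The ratio of 3' to 5' signal of the actin control transcript was 5.45 on the control array and 1.85 on the knockdown array, that of EF1A 2.92 and 1.5, and that of GAPDH 1.25 and 1.05. Poly-A spikes, bacterial transcripts added before labelling, gained at the 5' end against the 3' end by a median of 1.35 on the log2 scale (range 0.31 to 2.38, 12 pairs of probe sets), while hybridisation controls, added after labelling, moved by 0.03 (range -0.31 to 0.15, 12 pairs). Much of this shift was a loss at the 3' end of the spikes, where log2 ratios had a median of -0.93 (range -1.09 to -0.35). At their 5' end the median was 0.66 (range -0.62 to 1.43). The 3' ends of the chicken control genes had a median of -0.13. The spike pairs are repeat probe sets for the transcripts dap, lys, phe and thr, and the hybridisation pairs for bioB, bioC, bioD and cre. In genes with several measured probe sets, the brightest had a median log2 ratio of -0.05 and the dimmer ones 0.21. With the mean over a gene's measured probe sets, an alternative chosen after the data were seen, the pan-neuronal median was -0.38 and the proneural median -0.25. Markers of blood and surface ectoderm were higher on the same array, with medians of 0.65 and 0.68.

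**Figure D1:**
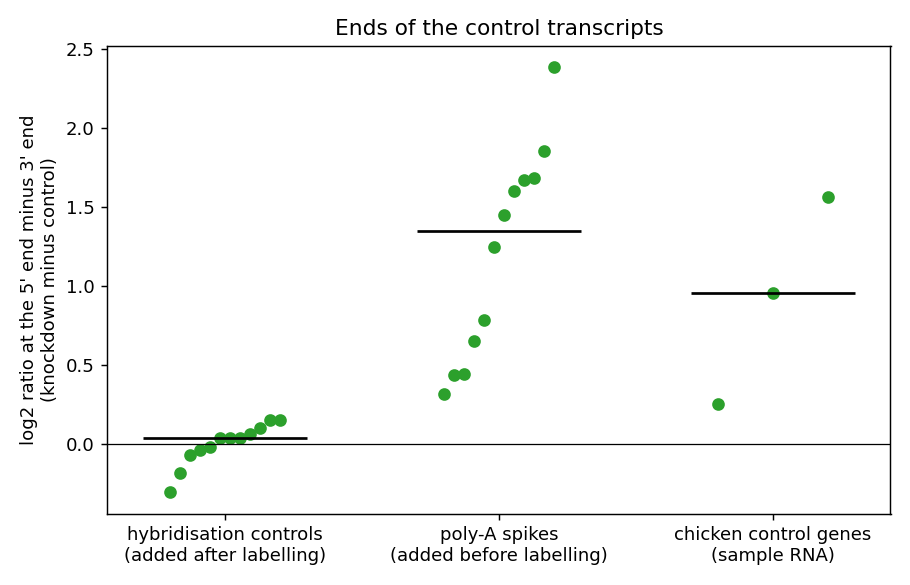
Each point is the log2 ratio (knockdown minus control) at the 5' end minus that at the 3' end for a pair of probe sets of a control transcript, and bars are medians. Poly-A spikes lie at a median of 1.35 and hybridisation controls at 0.03.

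Neural progenitor genes had a median log2 ratio of -0.05 over 34 measured members (-0.13 to 0.17; percentile 45.0 of random lists), and this median took either sign across the scalings. Of these genes, 26 lay within 1.5-fold, 3 were at least 2-fold higher and 0 at least 2-fold lower. The 3 were MEIS1 (131 and 423, log2 ratio 1.69), LIN28B (1.39) and the BMP target ID3 (1.24). SOX1 and SOX2, which mark neural progenitors, went in opposite directions, with log2 ratios of -0.77 and 0.76. PAX6 had a log2 ratio of -0.33 and the Notch target HES5 -0.08, though the other probe set of HES5 gave 0.90. Over the 11 measured Sox genes the median was -0.24 (-0.71 to 0.00, percentile 2.39), with SOX4 the only member past 2-fold and SOX17 at 0.72. Without the targets SOX4 and SOX11, an alternative chosen after the data were seen, the median of the other 9 was -0.17, inside the central 95% of its random lists (percentile 8.56). With the mean of all probe sets the median of the 11 was 0.0047.

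Dorsoventral patterning genes (28 measured, 2 higher and 0 lower by at least 2-fold) had a median log2 ratio of -0.05 (percentile 21.1), with SHH at 1.21, WNT1 at 1.13 and MSX2 at 0.98. HOX genes (20 measured, 1 higher, 2 lower) had a median of -0.22 (-0.34 to 0.11, percentile 0.46), with HOXC9 at -1.33, HOXB1 at -1.0 and HOXB2 at 1.01. The HOX median lay inside the central 95% of random lists under 6 settings, among them loess centring (percentile 4.05) and no filter (-0.077, percentile 12.5). Genes of the caudal neural plate had a median of -0.09 (16 measured, 0 past 2-fold, percentile 15.9), with CDX2 at -0.86 and TBXT at 0.40, and a median of 0.15 without a filter. Brain region genes had a median of -0.22 over 8 measured members (percentile 3.28), where OTX2 was at 1.25 and PAX2 at -1.08, and lay below the central 95% of random lists under 5 settings, among them quantile normalization (-0.38, percentile 1.75) and the mean of all probe sets (-0.35, percentile 0.2). With the filter at the 25th percentile it was 0.36 over 14 members (percentile 87.2). Neural crest genes (30 measured, 3 higher, 0 lower) had a median of 0.14 (percentile 91.3), with SNAI2 at 1.29. Axon guidance genes had a median of -0.09 (44 measured, 2 higher, 1 lower, percentile 4.99), with NTN3 at -1.0 and EFNA2 at 1.09, and a median of 0.12 without a filter on low signal (percentile 87.6).

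S phase genes had a median log2 ratio of 0.07 (41 measured, 2 higher, 0 lower, percentile 95.9), and the 2 were PRIM1, a primase subunit (1.34), and UHRF1 (1.13). G2 and M phase genes had a median of -0.16 (48 measured, 0 past 2-fold, percentile 0.410), a value that turned to 0.03 with the mean over measured probe sets. Genes of cell cycle exit had a median of -0.14 (12 measured, 2 higher, 0 lower, percentile 12.2). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, had signals of 410 and 1870 (log2 ratio 2.19), and CDKN2A was at 1.02. CDKN1A and the death receptor gene TNFRSF10B (1.64) were also the 2 members of the p53 and apoptosis list past 2-fold, of 30 measured (median 0.06, percentile 77.9, but 0.25 and percentile 98.2 with the mean over measured probe sets).

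Markers of several cell types outside the neural tube were higher on the knockdown array. Of 14 measured blood genes, 6 were at least 2-fold higher and 0 lower (median log2 ratio 0.65, -0.08 to 1.20, above all 10000 random lists). The 6 were 5 globin genes, among them HBZ (7609 and 19099, log2 ratio 1.33), HBA1 (1.30) and HBE (1.20), and the red cell anion exchanger gene SLC4A1 (1.49). Other red cell genes were even or lower, with TFRC at -0.32 and, named after their values were seen, ANK1 at -0.73 and RHCE at -0.078. Of 19 endothelial genes, 9 were at least 1.5-fold and 2 at least 2-fold higher, with 0 at least 1.5-fold lower (median 0.58, 0.16 to 0.72, percentile 99.5). CDH5, the endothelial cadherin, had signals of 415 and 1505 (log2 ratio 1.86), and TEK was at 1.11. The endothelial median lay inside the central 95% of random lists with the mean over measured probe sets (0.33, percentile 79.3) and without a filter on low signal (0.38, percentile 91.3). Of 18 surface ectoderm genes, 5 were at least 2-fold higher and 0 lower (median 0.68, 0.06 to 1.10, above all random lists), among them KRT7 (543 and 2239, log2 ratio 2.04) and ESRP2 (1.93). Of 14 notochord and endoderm genes, 4 were at least 2-fold higher and 0 lower (median 0.57, -0.10 to 1.10, percentile 99.7), namely GATA5 (1.38), NOTO (1.35), SHH (1.21) and APOA1 (1.20). With the filter at the 25th percentile that median was 0.22 (20 genes, percentile 67.7), inside the random lists. SHH is also a member of the dorsoventral patterning list. Of the 14 notochord and endoderm genes, 9 lay above 0 and 5 below, among the latter FOXA2 (-0.18), which is in both lists too. Somite genes had a median of 0.22 (27 measured, 4 higher, 0 lower, percentile 94.5), and the 4 were ACTC1 (3.57), ACTA1 (2.01), DES (1.34) and MYF5 (1.33).

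Heat shock, unfolded protein and immediate early genes had a median log2 ratio of 0.11 (38 measured, 5 higher, 1 lower, percentile 99.3), but came inside the central 95% of random lists with the filter at the 75th percentile (-0.0051, percentile 81.8), quantile normalization (percentile 97.1) and loess centring (percentile 97.3). ATF3 had a log2 ratio of 2.11, the small heat shock protein gene HSPB9 1.87 and HERPUD1 1.26, while ASNS, asparagine synthetase, was lower at -1.09. Interferon response genes had a median of 0.06 (16 measured, 1 higher, 0 lower, percentile 34.2), and that 1 was MOV10 (1.02). The interferon median was -0.078 with the mean of all probe sets, below the central 95% of random lists (percentile 1.9). With the filter at the 25th percentile it was 0.32 over 33 members (percentile 89.4). Genes of the RNA interference machinery had a median of -0.21 (10 measured, 0 past 2-fold, percentile 3.50), with DICER1 at 0.83, and a median of 0.28 with the mean of all probe sets (percentile 85.9). Hippo pathway genes had a median of 0.12 (19 measured, 3 higher, 0 lower, percentile 84.7), with FAT4 at 1.53, CYR61 at 1.03 and ANKRD1 at 1.01. Cell adhesion genes had a median of 0.06 (42 measured, 5 higher, 0 lower, percentile 49.0), with ITGAV at 1.55. Wnt, BMP and FGF genes had a median of 0.07 (59 measured, 2 higher, 0 lower, percentile 83.2), with RSPO3 at 0.92. All 62 ribosomal protein genes and all 20 reference genes lay within 1.5-fold, with medians of -0.07 and -0.10 (percentiles 34.6 and 20.9), and GAPDH was at -0.18.

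**Figure D2:**
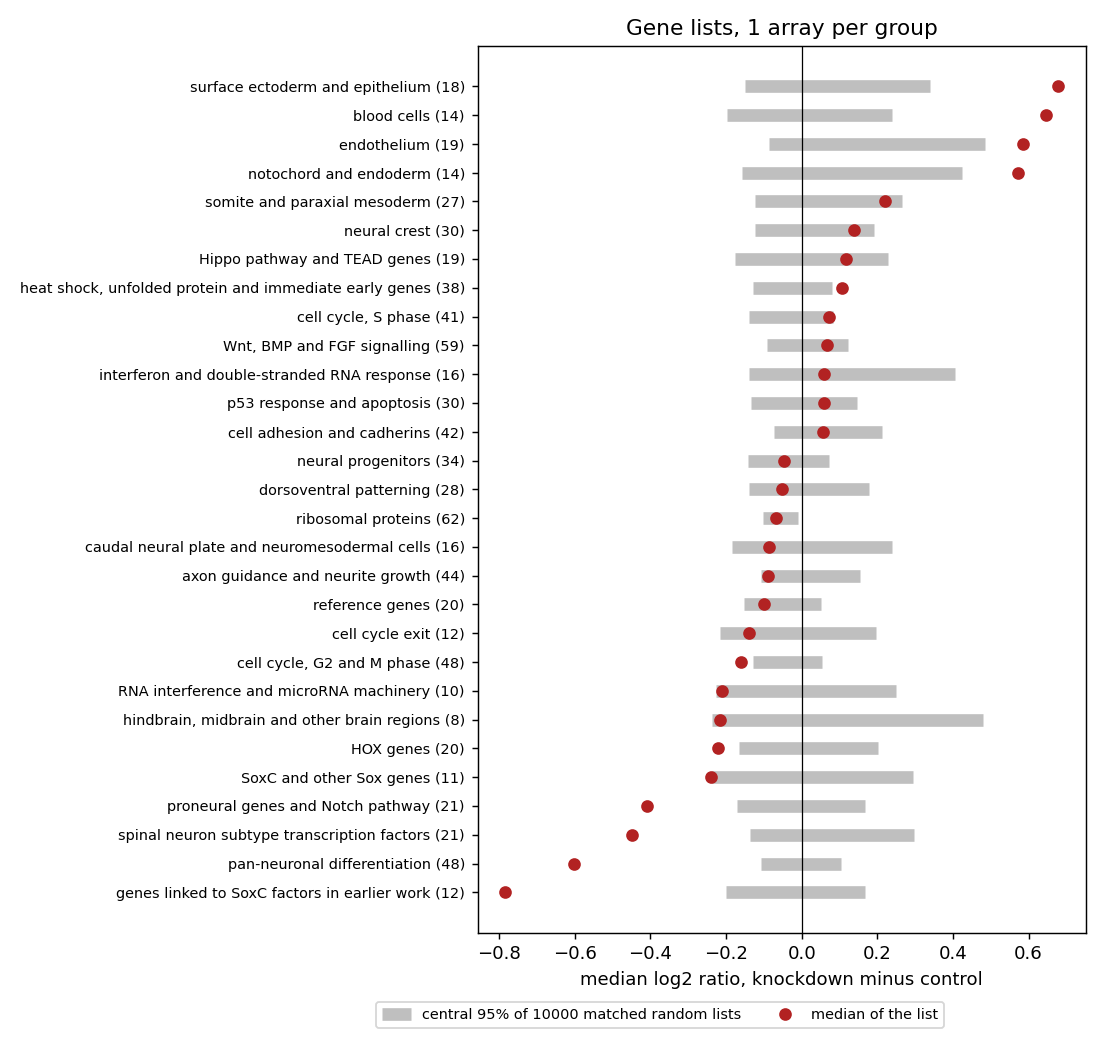
Points are median log2 ratios (knockdown minus control) of the 29 gene lists, with the number of measured genes in parentheses, and grey bars are the central 95% of 10000 random lists matched on mean signal. The SoxC-linked list lies lowest at -0.78 and the surface ectoderm list highest at 0.68.

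Of the 29 lists, 7 had a median below and 5 above the central 95% of their random lists, where lists of unrelated genes would give 1.45. The lists share members, and genes of a list can move together with any difference between the 2 samples. The number of lists outside is therefore no measure of an excess over chance. Under every scaling, filter and probe set rule tried, 3 lists stayed below the central 95% of random lists and 2 above it; these were the SoxC-linked, pan-neuronal and spinal subtype lists, and the blood and surface ectoderm lists. The other 7 (Sox, proneural, HOX, G2 and M phase, endothelium, notochord and endoderm, heat shock) came inside the central 95% under at least 1 setting, and the Sox list also did so without its 2 targets. In turn, 5 lists inside the central 95% came outside it under at least 1 setting (somite, brain region, p53, interferon, and Wnt, BMP and FGF). The medians of the progenitor, interferon, adhesion and ribosomal protein lists changed sign under quantile normalization and loess centring, and those of the dorsoventral, axon guidance, caudal, brain region, cell cycle exit and RNA interference lists under another filter or probe set rule. Median centring turned the medians of the S phase (-0.033), p53 (-0.047) and Wnt, BMP and FGF (-0.038) lists below 0, and those of the interferon and adhesion lists too.

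The highest log2 ratio among measured genes belonged to ACTC1 (559 and 6647, log2 ratio 3.57), followed among genes above background on both arrays by MYL1, which encodes a myosin light chain (2.69). MYL3 (2.38) and MYH15 (2.26), also myosin genes, were among the 12 highest, and so were MYL2 and ASTL, whose order is open because they lay below background in the control (at least 5.18-fold and 5.34-fold higher). The others were AvBD10, a defensin (2.63), the receptor gene TLR2A (2.57), the complement factor gene CFI (2.40), CLEC19A (2.21), CDKN1A and OLFML3 (2.14). The 12 lowest included DOCK11 (384 and 99.2, log2 ratio -1.95), the potassium channel gene KCND2 (-1.87), NUDT14 (-1.82), the actin-bundling protein gene FSCN1 (3757 and 1117, log2 ratio -1.75), ANP32E (-1.62), the transcription factor gene ST18 (-1.57) and ST6GAL1 (-1.497). QRFP (-1.84), BPIFB2 (-1.77), OPRL1 (-1.77), DUSP21 (-1.55) and LEKR1 (-1.499) made up the rest. Among the 10% of all 13008 genes with the highest signal, the lowest were NUP155 (-1.24), PPP1CB (-0.99), ELAVL4, TAGLN3 (-0.93) and DCLK1 (-0.89). The highest there were 4 globin genes (HBZ, HBA1, HBE and HBBR, 1.08 to 1.33) and MDH2 (1.11), whose other measured probe set gave the opposite direction. Measured probe sets also disagreed in direction for ANP32E and EFNA2 (1 of 2 in the direction given), DCLK1 (2 of 4), ELAVL2 and DCX (2 of 3) and UHRF1 (3 of 4).

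**Figure D3:**
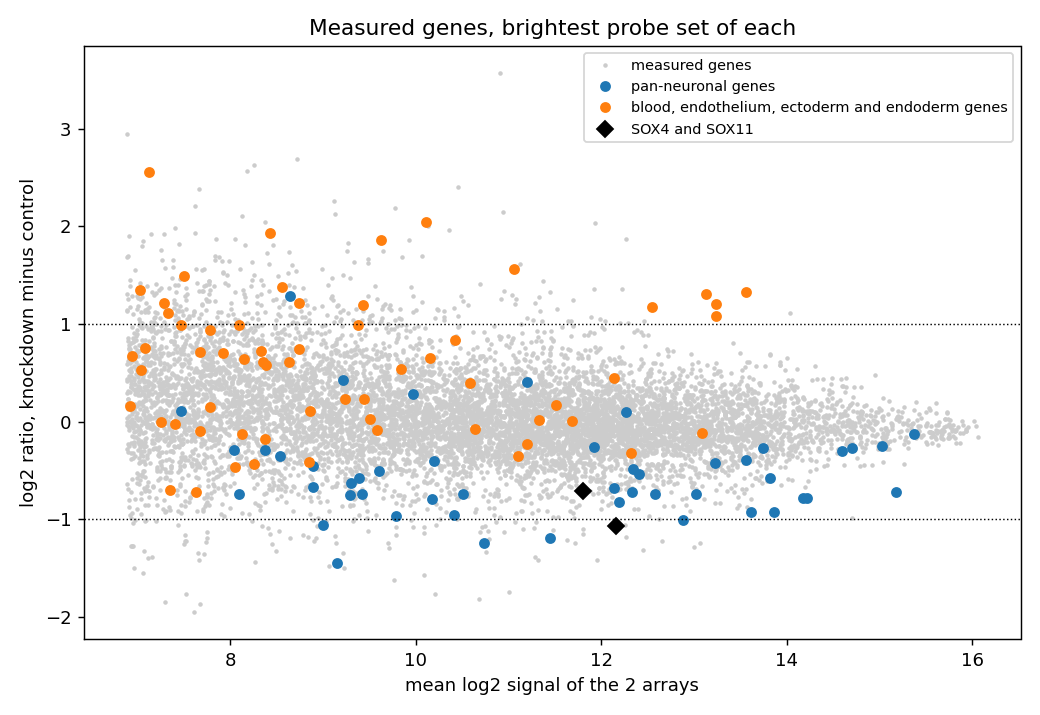
Each point is a measured gene, with the mean log2 signal of the 2 arrays on the x axis and the log2 ratio (knockdown minus control) on the y axis; dotted lines mark 2-fold. Pan-neuronal genes lie mostly below 0 (42 of 48), and SOX4 and SOX11 lie at -1.06 and -0.71.

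Of 9303 measured genes, 339 were at least 2-fold higher and 99 at least 2-fold lower on the knockdown array, so that 77.4% of these were higher. This split moved with the scaling of the arrays: 62.9% were higher after median centring (256 and 151 genes), which removes a shift of 0.10 in the median log2 ratio of chicken probe sets, 55.6% after quantile normalization (210 and 168) and 57.6% after loess centring (220 and 162). The spread between probe sets of a gene was the root mean square of their differences over the square root of 2. It was 0.54 in the dimmest of 10 signal groups and 0.18 in the brightest. Taken as a normal spread around 0, it gives 104 genes past 2-fold each way. In the upper 6 signal groups it gives 15.9 each way, against 60 higher and 41 lower observed. The differences were not centred, so the offset of the dimmer probe sets from the brightest (median 0.27) enlarges this spread. The dimmest group also had a median of 0.23 and not 0, so these numbers are rough. This spread leaves out the difference between samples of a group, so an excess over it does not show an effect of the knockdown. Without the marker genes of other cell types and the contractile genes, a count added after the data were seen, 300 genes were higher and 99 lower.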

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

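Probe sets for reporter and viral sequences are no part of the gene comparison, and 4 results from them (signals of bright probe sets and a count) were singled out as data outside it. The brightest of 57 reporter probe sets had a signal of 14072 on the knockdown array and 24239 on the control array (log2 ratio -0.78). This probe set was not identified with a sequence of the plasmids, so whether its signal measures GFP is not known here. The next brightest reporter probe set had 1572 and 1167 (log2 ratio 0.43). The brightest viral probe set had 3602 and 3006 (log2 ratio 0.26). Of 744 reporter and viral probe sets, 21 lay above background and were at least 2-fold higher on the knockdown array, with signals of at most 301, and 9 were so on the control array. No biological explanation was tested for these values.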

How the results depend on the processing

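No paired analysis was possible because each group has 1 sample. The mean over measured probe sets, the count without marker genes and the Sox list without its targets (median -0.17) were chosen after seeing the data. Counts depended on the setting: 210 higher and 168 lower genes with quantile normalization (210 and 97 shared with the reported ones), 220 and 162 with loess centring, 151 lower with median centring, 1300 and 652 without a filter on low signal, 815 and 316 at the 25th percentile, 71 and 46 at the 75th, 664 and 191 with the mean of all probe sets, 1061 and 531 at 1.5-fold, and 59 and 8 at 3-fold. More low-signal genes enter with a lower filter by construction. For the centrings the cause was not tested.

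With the mean of all probe sets, which averages in probe sets below background, the log2 ratios of SOX4 (1.05), SOX11 (0.98), DOCK11 (0.52), HOXB1 (0.39) and LEKR1 (0.32) reversed. MDH2 reversed to -0.85 with probe sets without suffix, since its probe sets disagree. Of 81 named genes past 2-fold, 5 reversed under some setting, 1 of them outside the mean of all probe sets. Over all alternatives, 18 of 1613 values of named genes changed sign, in 14 genes, 13 of them under a mean over probe sets; the 6 given are the targets and genes past 2-fold.

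The medians of the lists moved as follows, and the cause was not tested. The mean of all probe sets gave 0.0047 for Sox genes and 0.0034 for G2 and M phase genes (both reversed), -0.052 for HOX genes, -0.68 for SoxC-linked, -0.43 for pan-neuronal, -0.060 for proneural, -0.13 for subtype and 0.24 for heat shock genes. The mean of measured probe sets gave 0.027 for G2 and M phase (reversed), -0.086 for HOX, 0.33 for endothelium, -0.71 for SoxC-linked, 0.23 for heat shock, -0.38 for pan-neuronal and -0.25 for proneural genes. Median centring gave -0.26 for G2 and M phase, -0.89 for SoxC-linked, 0.0031 for heat shock, -0.71 for pan-neuronal and -0.51 for proneural genes. Quantile normalization gave 1.12 for contractile, 0.35 for endothelial and -0.70 for subtype genes, and loess centring 0.38 for endothelial and -0.68 for subtype genes. Without a filter the medians were -0.077 for HOX, 1.03 for contractile, 0.38 for endothelial and -0.48 for pan-neuronal genes, and at the 25th percentile 1.13 for contractile, 0.38 for endothelial, 0.22 for notochord and endoderm and -0.52 for pan-neuronal genes. At the 75th percentile they were 1.08 for blood, -0.19 for G2 and M phase, 0.64 for contractile, -0.0051 for heat shock (reversed), -0.70 for pan-neuronal and 0.35 for surface ectoderm genes. Of 371 list medians under the alternatives, 41 changed sign, in 16 lists; the 4 given as reversed are those of lists outside the central 95% of random lists. The regulator median was 1.12 at the 25th percentile and 1.12 without a filter. The pan-neuronal median stayed between -0.71 and -0.38 and below all random lists in all 13 settings. Among genes past 2-fold, the dimmer side lay at or below background in 3 of the 339 higher and 0 of the 99 lower genes. The filter on mean signal keeps most such cases out, so these counts do not show that low signal was no limit. Median signals of these genes were 307 for the higher and 596 for the lower ones.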

Other observations

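All tests in this part but that of the dimmer probe sets of pan-neuronal genes, and both muscle lists, were chosen after the values they bear on had been seen. Contractile muscle genes were higher on the knockdown array: of 26 measured, 18 were at least 2-fold higher and 0 lower, with a median log2 ratio of 1.37 (95% bootstrap interval 1.03 to 1.965), above all 10000 matched random lists. Besides ACTC1 and myosin genes, the 18 included the troponin genes TNNC2 (269 and 1170, log2 ratio 2.12), TNNC1 (1.965) and TNNT2 (1.75), and ACTN2 (1.45), named after their values were seen. Tropomyosin genes with high signal in the control were closer to even, with TPM1 at 14814 and 19185 (log2 ratio 0.37) and TPM3 at 0.13. Among muscle and heart regulators 4 were measured (median 0.48, percentile 79.1 of random lists), with GATA5 at 1.38 and MYF5 at 1.33 but MYOD1 at -0.36 and MEF2C at -0.80. With the filter at the 25th percentile the median was 1.12 over 11 regulators (percentile 99.8), and without a filter 1.12 over 13 (percentile 99.75). MYF6 (18.4 and 208.5), MYOG (31.9 and 162.2) and GATA6 (9.7 and 154.8), named after their values were seen, lay below background in the control and above it in the knockdown. The contractile list shares 3 members with the somite list, and it was drawn up because such genes led the highest ratios, so its median is no independent evidence.

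For these contractile genes, loess centring removes a fitted trend between the arrays that follows signal. It moved the median from 1.37 to 1.13, so the fitted trend made up a small part of that median. The median stayed above the central 95% of random lists (-0.21 to 0.19). The list was chosen for high ratios and would lie above random lists nearly by construction, so that comparison is no further evidence. A larger share of all non-neural cells alike stays open, because no fair comparison could be made with the pooled blood, endothelium, surface ectoderm and endoderm lists: the contractile list was chosen for high ratios, and leaving out the 40 highest genes removes 11 contractile but 4 other ones, which narrows the gap by construction (0.41, -0.26 to 0.90). A larger share of muscle or heart cells in particular stays open too. The 14 contractile genes that were neither named nor among the 40 highest had a median of 0.83, above random lists (-0.18 to 0.36). They come from the same list, written after the values were seen, so this median is no independent evidence for that share. The sort for GFP should remove cells that took up no plasmid, but its purity on each array is not known, and the brightest reporter probe set, not identified with a plasmid sequence, was lower on the knockdown array (14072 against 24239). Higher expression of these genes within electroporated neural cells may give the same values and was not tested.

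Pan-neuronal genes were lower on the knockdown array, and a lower share of neural cells among the sorted cells stays open. The progenitor genes were not lower alike: their median exceeded the pan-neuronal one by 0.56 (0.36 to 0.84). Their members went both ways, with 16 above and 18 below 0. Whether other sorted cells express members of that list was not measured, so this comparison cannot decide. Probe position under the labelling difference stays open too. Probe positions were not known, so dimmer probe sets stood in for them. The 42 dimmer probe sets of pan-neuronal genes lay 0.23 below those of other genes (log2 difference -0.23, -0.68 to -0.13). The 2 sets were not matched on signal. The median log2 ratio of measured genes fell with signal, from 0.23 in the dimmest of 10 signal groups to -0.06 in the brightest, so this gap cannot decide. The median of the 42 dimmer probe sets was only -0.01, so part of the size of the pan-neuronal difference may come from the arrays. An effect of the lower SOX4 and SOX11 levels remains a hypothesis, and so does a difference in stage or in the neurons' share between the embryos of each group, which was not tested.

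More genes were higher than lower on the knockdown array, 339 against 99. In 12 of 12 pairs of poly-A spike probe sets, the shift toward the 5' end was larger than in any hybridisation control. The spikes were added to the RNA as intact transcripts. RNA of the control sample degraded before labelling is thus argued against as the whole cause of the 5' to 3' difference between the arrays. These pairs are repeat measures of the transcripts dap, lys, phe and thr and are not independent. The spike shifts were not linked to the gene counts, so for the split of 339 against 99 such degradation stays open. For lys, and for thr in a repeat pair, both ends were lower on the knockdown array, the 3' end by more. Shorter labelled RNA on the control array stays open as a candidate source, with a median spike shift of 1.35 against -0.31 to 0.15 in the hybridisation controls. Within 3853 genes with several measured probe sets, the dimmer ones exceeded the brightest by a median of 0.27 (0.25 to 0.29), and in 72.2% of genes they were higher, which a difference in the amount of a gene's RNA alone would not give. Whether a part comes from the knockdown itself was not tested.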
